A study of Mus musculus with 24 samples.

How the data were processed

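RNA of sorted spleen B cells was measured on Affymetrix Mouse Genome 430 2.0 arrays, 24 in all, in 8 groups of 3. Cells were sorted by surface markers: follicular B cells as B220+ AA4.1- CD21int CD23+, marginal zone B cells as CD21high CD23low, and, among cells binding the hapten, memory B cells as IgG1+ CD38+ PNA-, germinal center B cells as IgG1+ CD38dull PNA+ and plasma cells as CD138+ with the lambda light chain. The deposited values are GCRMA summaries per probe set on the log2 scale, per the submitters' processing notes, which name no version. They were used as deposited, with no further normalization in the main analysis. Labels give no batch or scan date. Array medians ran from 2.39 to 2.86 and upper quartiles from 8.60 to 9.14, no pair of arrays was identical, and signal over background was limited by the floor of 2.15, where 36.8% to 43.1% of probe sets of an array lay. The number of arrays limits the precision of every value.

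The table held 45101 probe sets, of which 34958 had 1 gene symbol, 13 controls among them, 932 had several, and 9160 had none beside the other controls (64 controls in all). Each of 18194 genes was represented by its probe set with the highest mean over all arrays, and 11209 genes above the median of the array on at least 3 arrays were tested. Differences were estimated with limma (version 3.58.1, R 4.3.3) by 1 linear model with a mean for each of the 8 groups over all 24 arrays and moderated variances with the default prior. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 change at least 1 in size. There were 10 comparisons: memory B cells of day 7 and of day 40 against follicular B cells and against each other, germinal center against memory B cells at each day, germinal center B cells of day 40 against day 7, plasma cells against memory and against germinal center B cells of day 7, marginal zone against follicular B cells, and stimulated against unstimulated follicular B cells. The difference between the days in the germinal center minus memory change was tested as an interaction. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

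Fixed lists, 24 with 423 genes, were written before the data were examined; 388 of the genes had a probe set and 362 were tested. They cover the germinal center program, mitosis, DNA replication, somatic mutation and DNA repair, the plasma cell program, the secretory pathway, B cell identity, class II presentation, memory markers, quiescence, early activation, ribosome biogenesis, the BCL2 family, marginal zone markers, migration receptors, the toll-like receptor pathway, interferon-stimulated genes, glycolysis, oxidative phosphorylation, markers of T cells, myeloid cells, erythroid cells and platelets, and NK cells, and the sort markers. Lists were tested against the other genes with camera (limma) at a preset correlation of 0.01, adjusted over 242 list tests. Of these, 101 passed the threshold, and 11 of the 101 also passed it with an estimated correlation. Lists of macrophage, neutrophil, eosinophil, monocyte and dendritic cell, and tissue dissociation genes were added after the data were examined.

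Genes were named by a rule written before the data were examined: per comparison the 8 largest rises and the 8 largest falls among called genes whose 3 arrays of either group all lie above those of the other, index genes (Bcl6, Prdm1, Xbp1, Irf4, Pax5, Bach2, Myc, Bcl2, Cd80 and Mki67), up to 4 called members of each list described, and the sort markers. Placeholder names and immunoglobulin and T cell receptor segments were left out, and the text leaves out genes from the smallest change upward. Chance alone separates 3 arrays from 3 for 10% of genes. A change was taken as a lower bound where each of the 3 arrays of a group lay at or below its own median.

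Alternatives were no filter on dim genes, a stricter filter at the 75th percentile, quantile normalization, arrays shifted to the same median, an offset of 16 before the logarithm, the mean of a gene's probe sets, probe sets with cross-hybridizing names left out, a trended and robust prior, array weights, only the compared groups in the fit, no minimum change, a block for the replicate number, and each array left out in turn. Leaving out the array with the fewest values at the floor of each group, the share at the floor as a covariate, and list counts without doubted arrays were added after the data were examined. Calls were also recounted for other splits of the same arrays. The procedure was tested on simulated data, with 50 changed genes per size: for day 40 against day 7 memory cells it recovered 38% at a log2 change of 1 and 92% at 1.5, with 2 false calls, for germinal center against memory cells at day 7 it recovered 44% and 88%, with 8 false calls, and for marginal zone against follicular cells 32% and 80%, with 6 false calls. Simulated noise was normal, and changed genes were drawn only from those with a mean well above the floor and the array medians. Recovery was thus not tested for dim genes or for changes that start at the floor. A simulated change of 1 lies at the minimum for a call, which limits its recovery. Genes without a probe set carrying 1 symbol were left out, as were stimulated marginal zone cells, which were not analysed here.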

Results

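Gene expression was measured in spleen B cell populations of female C57BL/6 mice on 24 whole-genome arrays, 3 for each of 8 groups. Naive cells were sorted as follicular B cells and as marginal zone B cells, the population at the border of the follicle. Follicular B cells were also cultured for 6 h with antibodies against IgM (10 µg/ml) and CD40 (2 µg/ml), which engage the antigen receptor and the receptor for T cell help. From mice immunized with the hapten NP on a carrier protein, hapten-binding IgG1 memory B cells and germinal center B cells were sorted at day 7 and at day 40, and plasma cells at day 7. Stimulated marginal zone cells, which the design text mentions, were not analysed here.

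Signals ran from a floor of 2.15 to 16.43 on the log2 scale, and array medians from 2.39 to 2.86. Between 36.8% and 43.1% of probe sets lay at the floor on each array. Arrays of the same group correlated at r = 0.961 to 0.996 over 24 pairs, across genes, which are not independent replicates. The labels do not say whether the 3 samples of a group came from separate animals. P-values thus measure only the spread between samples within groups, which may be technical. Changes below are log2 changes ± SE between groups of 3 arrays, and levels are log2 signals ± SD (n = 3). SE and p rest on a moderated variance pooled over all 8 groups, not on the compared groups alone. Groups at the floor with an SD of 0 lower it: Ackr3 in memory cells of day 40 against day 7 had an SE of 0.50, with SDs of 1.82 and 0. The number of arrays limits the precision of each value.

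Memory B cells of day 7 were compared with naive follicular B cells to ask what sets memory cells apart from their naive counterparts. Parm1 (chromosome 5) rose by 10.82 ± 0.16 (SE), to 13.30 ± 0.16 from 2.48 ± 0.08 (SD, n = 3, adjusted p = 6.15e-19). Nfil3 (chromosome 13), a basic leucine zipper transcription factor, rose by 10.59 ± 0.29 (SE), to 12.98 ± 0.49 from 2.39 ± 0.22 (SD, n = 3, adjusted p = 3.64e-15). Other large rises were those of Slpi (10.34 ± 0.20), Rgs1 (10.26 ± 0.36), Tent5c (10.18 ± 0.22), Ackr2 (9.70 ± 0.27), Pik3r6 (9.40 ± 0.23) and Fosl2 (9.38 ± 0.63). None had an adjusted p above 1.82e-09. Slpi encodes a secreted protease inhibitor, Rgs1 a regulator of G protein signalling and Fosl2 a member of the AP-1 family. The largest falls were those of Crip3 (-7.34 ± 0.30), Pde2a (-6.90 ± 0.44), B3gnt8 (-5.98 ± 0.31), Rtp4 (-5.62 ± 0.36), Mapk12 (-5.52 ± 0.26) and Tnik (-5.45 ± 0.42). The highest adjusted p was 1.38e-08. Pik3r6 and Fosl2 lay at background in follicular cells, that is, each of the 3 arrays was at or below its own median, so their rises are lower bounds.

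Cell division genes were the largest group: 22 of 24 rose, 0 fell and 2 were not called (23 and 0 adjusted over the list alone). For the mitosis list the median change was 5.35, with an adjusted p = 1.51e-15 (adjusted p = 0.209 with an estimated correlation). Ube2c (7.71 ± 0.45), Kif23 (6.58 ± 0.45), Kif11 (6.25 ± 0.64) and Ccnb2 (5.99 ± 0.56) led it, and the proliferation marker Mki67 rose by 5.45 ± 0.50. In the germinal center program, 10 of 16 rose, 0 fell and 6 were not called (11 and 0 adjusted over the list alone), among them Plxnb2 (6.21 ± 0.73), Hmmr (5.75 ± 0.93) and S1pr2 (4.69 ± 0.91). For the germinal center program list the median change was 3.10, with an adjusted p = 5.52e-06 (adjusted p = 0.273 with an estimated correlation). Replicate 1 of the day 7 memory cells lay closer to germinal center B cells than the other replicates did (mean r with the day 7 germinal center arrays 0.947, against 0.903 and 0.910). Without it 20 mitosis genes rose and 0 fell (median 4.39), and 9 germinal center genes rose and 1 fell (median 2.51). Some germinal center genes were high in replicate 1 alone: Gcsam stood at 9.21 against a mean of 2.33 in the others, Mef2b at 9.31 against 2.60 and Mybl1 at 9.95 against 3.44. Plxnb2 hardly differed (10.38 against 10.255). DNA replication genes depended on replicate 1: 4 of 24 rose, 0 fell and 20 were not called (4 and 0 adjusted over the list alone), but without it 2 rose and 4 fell. For the DNA replication list the median change was 0.40, and the list did not pass its test (adjusted p = 0.120).

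Memory cell markers were higher: 7 of 14 rose, 1 fell and 6 were not called (7 and 1 adjusted over the list alone). For the memory marker list the median change was 1.35, with an adjusted p = 1.66e-04 (adjusted p = 0.209 with an estimated correlation). Cxcr3 (8.18 ± 0.25), Nt5e (8.00 ± 0.33), Zbtb32 (7.58 ± 0.35) and Cd80 (4.32 ± 0.47) led them (Cxcr3 is a chemokine receptor, Nt5e is CD73 and Cd80 a costimulatory ligand), with follicular cells at background for Nt5e, Zbtb32 and Cd80. In the plasma cell program, 10 of 18 rose, 0 fell and 8 were not called (11 and 1 adjusted over the list alone), including Slpi (10.34 ± 0.20), Tent5c (10.18 ± 0.22) and Jchain (6.74 ± 0.64) for the J chain of secreted antibody. For the plasma cell program list the median change was 1.43, with an adjusted p = 5.63e-08 (adjusted p = 0.0402 with an estimated correlation). Prdm1, the plasma cell regulator Blimp-1, rose by 1.89 ± 0.55, a call that ended without memory replicate 2 (1.39), without memory replicate 3 (1.59), with only these groups in the fit, and with the array that had the fewest values at the floor left out of each group (1.51). Early activation genes, induced within hours of receptor signalling, were higher too: 11 of 23 rose, 0 fell and 12 were not called (12 and 0 adjusted over the list alone). For the early activation list the median change was 1.51, with an adjusted p = 3.56e-06 (adjusted p = 0.209 with an estimated correlation). Nr4a3 (9.14 ± 0.26), Fosb (7.53 ± 1.12) and Nr4a1 (4.71 ± 0.36) rose most, and a separate list of tissue dissociation and heat shock genes, added after the data were examined, had 9 of 20 genes higher and 0 lower. Of 17 interferon-stimulated genes, 7 fell, and 4 fell without memory replicate 1, but the list did not pass its test (adjusted p = 0.0734). Of 14 myeloid markers with a probe set 9 were tested, and 3 rose, Lyz2 (5.53 ± 1.42), Mpeg1 (3.54 ± 0.60) and Adgre1 (1.39 ± 0.32). The myeloid list did not pass its test (camera, adjusted p = 0.118), and its median was 1.39, or 0.565 without memory replicate 1. In all, 1029 genes rose and 1031 fell in day 7 memory cells.

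Memory B cells of day 40 were compared with the same follicular cells, to describe memory long after immunization. Nfil3 (chromosome 13) rose by 10.77 ± 0.29 (SE), to 13.16 ± 0.14 from 2.39 ± 0.22 (SD, n = 3, adjusted p = 2.82e-15). Parm1 (10.69 ± 0.16), Fosl2 (10.55 ± 0.63), Nr4a3 (9.77 ± 0.26), Hspa1b (9.66 ± 0.84), Tent5c (9.63 ± 0.22) and Rgs1 (9.24 ± 0.36) followed. These had adjusted p values up to 8.40e-08, and the rise of Fosl2 is a lower bound because follicular cells lay at background. Hspa1b encodes an inducible heat shock protein. Gpat3 (chromosome 5), an enzyme of triglyceride synthesis, fell by 6.30 ± 0.50 (SE), to 4.99 ± 0.79 from 11.29 ± 0.15 (SD, n = 3, adjusted p = 2.54e-08). Next came Pde2a (-5.59 ± 0.44), Cldn10 (-5.52 ± 0.52), Il12a (-5.44 ± 0.42), B3gnt8 (-5.40 ± 0.31) and Crip3 (-5.31 ± 0.30). Adjusted p values were at most 2.51e-07.

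Early activation genes had the lowest p in the list tests (camera) at this day: 15 of 23 rose, 0 fell and 8 were not called (15 and 0 adjusted over the list alone). Across the early activation list the median change was 2.09, with an adjusted p = 5.59e-13 (adjusted p = 0.0402 with an estimated correlation). Nr4a3 (9.77 ± 0.26), Fosb (8.17 ± 1.12), Nr4a1 (5.72 ± 0.36) and Junb (3.89 ± 0.30) led it. The list of tissue dissociation and heat shock genes moved with it: 15 of 20 rose and 0 fell, with an adjusted p = 1.45e-10 over the comparisons (adjusted p = 0.0293 with an estimated correlation). Memory markers were again higher: 8 of 14 rose, 0 fell and 6 were not called (8 and 1 adjusted over the list alone), led by Nt5e (8.86 ± 0.33), Cxcr3 (5.74 ± 0.25) and Cd80 (4.33 ± 0.47). Across the memory marker list the median change was 1.68, with an adjusted p = 1.73e-06 (adjusted p = 0.119 with an estimated correlation). Follicular cells lay at background for Nt5e and Cd80, so these rises are lower bounds. For cell division, 17 of 24 rose, 0 fell and 7 were not called (19 and 0 adjusted over the list alone), with Ube2c (5.51 ± 0.45), Nusap1 (5.35 ± 0.62) and Kif23 (5.15 ± 0.45) at the top. Across the mitosis list the median change was 3.91, with an adjusted p = 2.29e-12 (adjusted p = 0.281 with an estimated correlation). Within the germinal center program, 10 of 16 rose, 0 fell and 6 were not called (12 and 0 adjusted over the list alone), with Plxnb2 (5.61 ± 0.73), Rgs13 (5.15 ± 0.89) and S1pr2 (4.99 ± 0.91) as examples. Across the germinal center program list the median change was 3.29, with an adjusted p = 2.75e-07 (adjusted p = 0.209 with an estimated correlation). Gcsam stood at 6.33, 7.46 and 2.71 in the day 40 memory arrays, against 2.15 in each follicular array. Germinal center cells mixed into several of these memory arrays would not show as a difference between replicates, and this was not tested.

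Interferon-stimulated genes were lower in day 40 memory cells: 0 of 17 rose, 9 fell and 8 were not called (0 and 10 adjusted over the list alone), led by Usp18 (-2.82 ± 0.62), Oasl2 (-2.78 ± 0.48) and Mx1 (-2.46 ± 0.42). For the interferon list the median change was -1.38, with an adjusted p = 2.18e-05 (adjusted p = 0.263 with an estimated correlation). Among migration receptors, 6 of 17 rose, 1 fell and 10 were not called (7 and 2 adjusted over the list alone), with Cxcr3 (5.74 ± 0.25), S1pr2 (4.99 ± 0.91) and S1pr3 (4.11 ± 0.31) up and S1pr4 (-2.24 ± 0.33) down. For the migration receptor list the median change was 0.79, with an adjusted p = 1.27e-04 (adjusted p = 0.119 with an estimated correlation). Of the plasma cell list, 7 of 18 rose, 2 fell and 9 were not called (7 and 2 adjusted over the list alone): Tent5c (9.63 ± 0.22), Slpi (8.39 ± 0.20) and Jchain (5.68 ± 0.64) rose, while Sdc1 (-3.29 ± 0.64), the plasma cell marker CD138, fell. Across the plasma cell program list the median change was 0.55, with an adjusted p = 6.66e-04 (adjusted p = 0.209 with an estimated correlation). Bcl2 did not change detectably, 0.12 ± 0.31, adjusted p = 0.877, nor did Prdm1 (1.07 ± 0.55, adjusted p = 0.182), whose estimate came to 0.48 without memory replicate 2. Of the 9 myeloid markers tested 3 rose, S100a9 (8.05 ± 2.80), Lyz2 (6.33 ± 1.42) and Mpeg1 (2.57 ± 0.60), and the rise of S100a9 is a lower bound. The myeloid list did not pass its test (camera, adjusted p = 0.0913). Without plasma replicate 2, 2 were called. With the array that had the fewest values at the floor left out of each group, 1 was called, with a list median of 0.37 against 1.54. The comparison called 810 genes that rose and 733 that fell in day 40 memory cells.

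Memory cells of the early and the late day were then compared directly. Mapk12 (chromosome 15), a p38 kinase, rose by 6.98 ± 0.26 (SE), to 9.44 ± 0.24 from 2.46 ± 0.35 (SD, n = 3, adjusted p = 3.85e-12). Ackr3 (6.47 ± 0.50), Bmpr1a (6.04 ± 0.36), Tox2 (5.48 ± 0.68), Osbpl3 (5.34 ± 0.47) and Gnaz (4.89 ± 0.18) were also higher at day 40. None had an adjusted p above 4.32e-05 (Ackr3 is an atypical chemokine receptor and Bmpr1a a receptor for bone morphogenetic proteins). Ppfia4 (chromosome 1) fell by 6.41 ± 0.36 (SE), to 2.60 ± 0.09 from 9.02 ± 0.43 (SD, n = 3, adjusted p = 2.53e-09). Avil (-5.76 ± 0.61), Morrbid (-5.75 ± 0.48), Ptgr1 (-5.35 ± 0.34), S100a4 (-5.32 ± 0.50) and Emp1 (-5.28 ± 0.44) were lower at day 40 as well. The highest adjusted p was 5.34e-06. S100a4 encodes a calcium-binding protein. Background in the lower group makes the changes of Ackr3, Avil and Emp1 lower bounds, and the call of Tox2 ended with only these groups in the fit.

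Of the plasma cell genes at day 40, 1 of 18 rose, 4 fell and 13 were not called (1 and 5 adjusted over the list alone), the falls led by Fkbp11 (-4.42 ± 0.26), Tnfrsf17 (-2.79 ± 0.18), Slpi (-1.95 ± 0.20) and Slamf7 (-1.92 ± 0.27), of which Tnfrsf17 fell to background, a lower bound. In the plasma cell program list the median change was -0.68, with an adjusted p = 1.01e-05 (adjusted p = 0.0906 with an estimated correlation). For mitosis, 0 of 24 rose, 6 fell and 18 were not called (0 and 9 adjusted over the list alone), among them Cenpe (-2.77 ± 0.72), Ttk (-2.57 ± 0.72) and Aurkb (-2.25 ± 0.53), but without memory day 7 replicate 1 the number that fell was 1 and the median -0.41. In the mitosis list the median change was -1.37, with an adjusted p = 2.59e-07 (adjusted p = 0.426 with an estimated correlation). Of 14 memory markers, Zbtb32 (-3.85 ± 0.35) and Cxcr3 (-2.44 ± 0.25) fell and Il9r (1.79 ± 0.36) rose, and the call of Il9r ended with the array that had the fewest values at the floor left out of each group. In the memory marker list the median change was 0.12, and the list did not pass its test (adjusted p = 0.674). Its mean had the other sign (-0.22). Of the early activation genes, 2 of 23 were called higher, Junb (1.24 ± 0.30) and Egr3 (1.20 ± 0.20), and 3 adjusted over the list alone; 1 was called with the low-floor arrays left out in that way. In the early activation list the median change was 0.63, with an adjusted p = 2.40e-05 (adjusted p = 0.222 with an estimated correlation). The dissociation and heat shock list moved the same way, with 2 of 20 genes higher and 0 lower, a median of 0.75 and an adjusted p = 6.98e-05 (adjusted p = 0.198 with an estimated correlation). Without memory day 7 replicate 1 4 germinal center genes and 3 DNA replication genes were higher at day 40, against 0 and 0 with it. No detectable change was found for Bcl6 (0.29 ± 0.18, adjusted p = 0.354), Bcl2 (0.70 ± 0.31, adjusted p = 0.167) or Cd80 (0.01 ± 0.47). Of 11209 genes tested, 306 were higher and 256 were lower at day 40, counts that depended on the fit: 105 and 94 with only these groups in it, and 505 and 403 with array weights. With the array that had the fewest values at the floor left out of each group, an alternative added after the data were examined, the counts were 150 and 140.

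Germinal center and memory B cells of the same immune response were compared at day 7. Gcsam (chromosome 16), a germinal center signalling adaptor, rose by 7.49 ± 1.28 (SE), to 12.11 ± 0.40 from 4.62 ± 3.97 (SD, n = 3, adjusted p = 1.23e-04). Otub2 (6.59 ± 0.78), Dnase1 (6.56 ± 0.31), Gpsm2 (6.55 ± 1.02), Pbk (6.13 ± 1.09) and Adhfe1 (6.09 ± 0.96) rose next. These had adjusted p values up to 1.80e-04. S100a6 (chromosome 3), a calcium-binding protein, fell by 10.46 ± 0.75 (SE), to 2.87 ± 0.36 from 13.33 ± 0.44 (SD, n = 3, adjusted p = 3.88e-09). Pml (-10.36 ± 0.48), Sspn (-10.21 ± 0.36), S100a10 (-9.43 ± 0.67), Pik3r6 (-9.40 ± 0.23), Fosl2 (-9.26 ± 0.63) and Ccr6 (-9.23 ± 0.29) were also much lower in germinal center cells. Adjusted p values were at most 3.88e-09, and the survival factor Bcl2 fell by 6.20 ± 0.31. The falls of Sspn and Pik3r6 are lower bounds, since germinal center cells lay at background. Calls of Gcsam and Pbk ended with only these groups in the fit, where the memory replicates lay far apart (Gcsam 9.21 in replicate 1 against a mean of 2.33 in the other replicates).

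Cell cycle genes were higher in germinal center cells: for mitosis, 24 of 24 rose, 0 fell and 0 were not called (24 and 0 adjusted over the list alone), and for DNA replication, 23 of 24 rose, 0 fell and 1 was not called (23 and 0 adjusted over the list alone). The mitosis list had a median change of 3.39, with an adjusted p = 5.11e-10 (adjusted p = 0.333 with an estimated correlation). Across the DNA replication list the median change was 2.65, with an adjusted p = 4.89e-11 (adjusted p = 0.281 with an estimated correlation). Plk1 (5.80 ± 0.68), Aurka (5.23 ± 0.72) and Cenpf (4.84 ± 0.79) were among the mitotic genes and Mcm10 (5.88 ± 0.81) and Cdc45 (5.35 ± 0.90) among the replication genes. Somatic mutation and repair genes rose with them: 13 of 16 rose, 0 fell and 3 were not called (13 and 0 adjusted over the list alone), with Exo1 (4.62 ± 0.70), Brca1 (4.25 ± 0.74) and Lig4 (3.75 ± 0.63) the largest. For the mutation and repair list the median change was 1.54, with an adjusted p = 6.12e-07 (adjusted p = 0.209 with an estimated correlation). The germinal center program held Gcsam (7.49 ± 1.28), Mef2b (5.91 ± 1.16), S1pr2 (4.91 ± 0.91) and Mybl1 (4.48 ± 1.10): 11 of 16 rose, 1 fell and 4 were not called (11 and 1 adjusted over the list alone). In the germinal center program list the median change was 3.02, with an adjusted p = 8.58e-04 (adjusted p = 0.407 with an estimated correlation). With the array that had the fewest values at the floor left out of each group, 7 of them rose. Bcl6, the master regulator of the germinal center, rose by 1.31 ± 0.18, to 13.94 from 12.63.

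Memory markers were lower in germinal center cells: 0 of 14 rose, 9 fell and 5 were not called (0 and 9 adjusted over the list alone). The memory marker list had a median change of -3.52, with an adjusted p = 2.08e-09 (adjusted p = 0.0552 with an estimated correlation). Ccr6 (-9.23 ± 0.29), Cxcr3 (-8.22 ± 0.25), Zbtb32 (-7.06 ± 0.35) and Hhex (-6.72 ± 0.61) led the fall. Early activation genes were lower: 0 of 23 rose, 15 fell and 8 were not called (0 and 16 adjusted over the list alone), including Ier2 (-3.62 ± 0.41), Myc (-3.23 ± 0.63) and Egr3 (-3.03 ± 0.20). The early activation list had a median change of -1.71, with an adjusted p = 1.41e-07 (adjusted p = 0.136 with an estimated correlation). The dissociation and heat shock list moved the same way, with 7 of 20 genes lower and 1 higher, a median of -0.89 and an adjusted p = 0.0433 (adjusted p = 0.379 with an estimated correlation). Migration receptors were lower as a group, with Ccr6 (-9.23 ± 0.29), Cxcr3 (-8.22 ± 0.25) and Ccr7 (-5.12 ± 0.72) down and S1pr2 (4.91 ± 0.91), which confines cells to the follicle, up: 1 of 17 rose, 9 fell and 7 were not called (1 and 9 adjusted over the list alone). Across the migration receptor list the median change was -1.53, with an adjusted p = 1.25e-05 (adjusted p = 0.0814 with an estimated correlation). Interferon-stimulated genes followed: 0 of 17 rose, 11 fell and 6 were not called (0 and 11 adjusted over the list alone), with Mx1 (-6.22 ± 0.42), Gbp2 (-5.02 ± 0.57) and Ifit3 (-4.35 ± 0.48). Across the interferon list the median change was -1.47, with an adjusted p = 1.16e-05 (adjusted p = 0.240 with an estimated correlation). Quiescence genes such as Klf3 (-6.74 ± 0.69), Pik3ip1 (-4.99 ± 0.45) and S1pr1 (-3.75 ± 0.57) were lower as well: 1 of 20 rose, 10 fell and 9 were not called (1 and 10 adjusted over the list alone). For the quiescence list the median change was -1.14, with an adjusted p = 0.00299 (adjusted p = 0.179 with an estimated correlation). In all, 1299 genes rose and 1356 fell in germinal center cells.

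At day 40 the same comparison was made on separate arrays. Nrep (chromosome 18) rose by 8.11 ± 0.11 (SE), to 10.44 ± 0.06 from 2.33 ± 0.30 (SD, n = 3, adjusted p = 3.83e-20). Melk (7.77 ± 0.73), Plk1 (7.71 ± 0.68), E2f7 (7.53 ± 1.01), Kif2c (7.50 ± 0.73) and Aurka (7.46 ± 0.72) came next. None had an adjusted p above 6.09e-06 (Plk1 and Aurka are mitotic kinases, and the rise of E2f7 is a lower bound because memory cells lay at background). Ccr6 (chromosome 17), a chemokine receptor, fell by 10.11 ± 0.29 (SE), to 3.45 ± 0.82 from 13.56 ± 0.21 (SD, n = 3, adjusted p = 5.72e-15). Scml4 (-9.65 ± 0.32), Bcl2 (-9.37 ± 0.31), Sspn (-9.28 ± 0.36), Pml (-9.22 ± 0.48) and Tent5a (-9.09 ± 0.36) were lower too. The highest adjusted p was 2.65e-11.

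Cell cycle lists rose in germinal center cells: for mitosis, 24 of 24 rose, 0 fell and 0 were not called (24 and 0 adjusted over the list alone), and for DNA replication, 22 of 24 rose, 0 fell and 2 were not called (22 and 0 adjusted over the list alone). For the mitosis list the median change was 5.14, with an adjusted p = 2.29e-12 (adjusted p = 0.281 with an estimated correlation). In the DNA replication list the median change was 2.90, with an adjusted p = 9.71e-09 (adjusted p = 0.338 with an estimated correlation). Ttk (7.16 ± 0.72) and Cenpf (7.00 ± 0.79) were high among the mitotic genes and Mcm10 (7.11 ± 0.81), Cdc45 (7.02 ± 0.90) and Gins2 (6.71 ± 0.84) among the replication genes. In the germinal center program, led by Gcsam (6.78 ± 1.28), Mef2b (6.61 ± 1.16) and Mybl1 (6.44 ± 1.10), 13 of 16 rose, 1 fell and 2 were not called (13 and 1 adjusted over the list alone). The germinal center program list had a median change of 3.61, with an adjusted p = 0.00133 (adjusted p = 0.426 with an estimated correlation). For somatic mutation and repair, 13 of 16 rose, 0 fell and 3 were not called (13 and 0 adjusted over the list alone), with Exo1 (5.75 ± 0.70), Lig4 (4.37 ± 0.63) and Brca1 (4.35 ± 0.74) at the top. Across the mutation and repair list the median change was 1.54, with an adjusted p = 3.68e-05 (adjusted p = 0.282 with an estimated correlation).

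Memory markers were lower in germinal center cells of day 40: 2 of 14 rose, 10 fell and 2 were not called (2 and 10 adjusted over the list alone), with Ccr6 (-10.11 ± 0.29), Bcl2 (-9.37 ± 0.31), Ski (-6.78 ± 0.33) and Pdcd1lg2 (-6.41 ± 0.50) falling most. For the memory marker list the median change was -3.57, with an adjusted p = 1.45e-07 (adjusted p = 0.0906 with an estimated correlation). Migration receptors showed Itgb7 (-8.19 ± 0.46), Ccr7 (-7.89 ± 0.72) and Gpr183 (-6.15 ± 0.34) beside Ccr6: 2 of 17 rose, 10 fell and 5 were not called (2 and 10 adjusted over the list alone). In the migration receptor list the median change was -2.16, with an adjusted p = 6.78e-06 (adjusted p = 0.0706 with an estimated correlation). Marginal zone markers, led by Cd1d1 (-8.35 ± 0.20) and Asb2 (-4.37 ± 0.24), fell as well: 0 of 12 rose, 9 fell and 3 were not called (0 and 10 adjusted over the list alone). For the marginal zone marker list the median change was -2.20, with an adjusted p = 3.56e-06 (adjusted p = 0.0906 with an estimated correlation). Early activation genes were lower, Nr4a3 (-3.93 ± 0.26) and Ier2 (-3.81 ± 0.41) among them, although Ier3 (3.78 ± 0.24) rose from background, a lower bound, as is the fall of Cd1d1: 1 of 23 rose, 11 fell and 11 were not called (1 and 11 adjusted over the list alone). For the early activation list the median change was -1.10, with an adjusted p = 1.48e-05 (adjusted p = 0.209 with an estimated correlation). The dissociation and heat shock list had 8 of 20 genes lower and 1 higher. In the quiescence list, Klf3 (-7.85 ± 0.69) and S1pr1 (-5.46 ± 0.57) fell among others: 1 of 20 rose, 10 fell and 9 were not called (1 and 10 adjusted over the list alone). Across the quiescence list the median change was -1.17, with an adjusted p = 0.00133 (adjusted p = 0.131 with an estimated correlation). The comparison called 1713 genes that rose and 1415 that fell in germinal center cells of day 40. Across the 11209 genes, the germinal center minus memory difference at day 7 correlated with that at day 40 (Pearson r = 0.842, Spearman rho = 0.779, described across genes, which are not independent replicates). Genes higher at both days numbered 1041, where independent lists of these sizes would share 198.5, and genes lower at both numbered 958 against 171.2, while 15 were called in opposite directions.

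**Figure D1:**
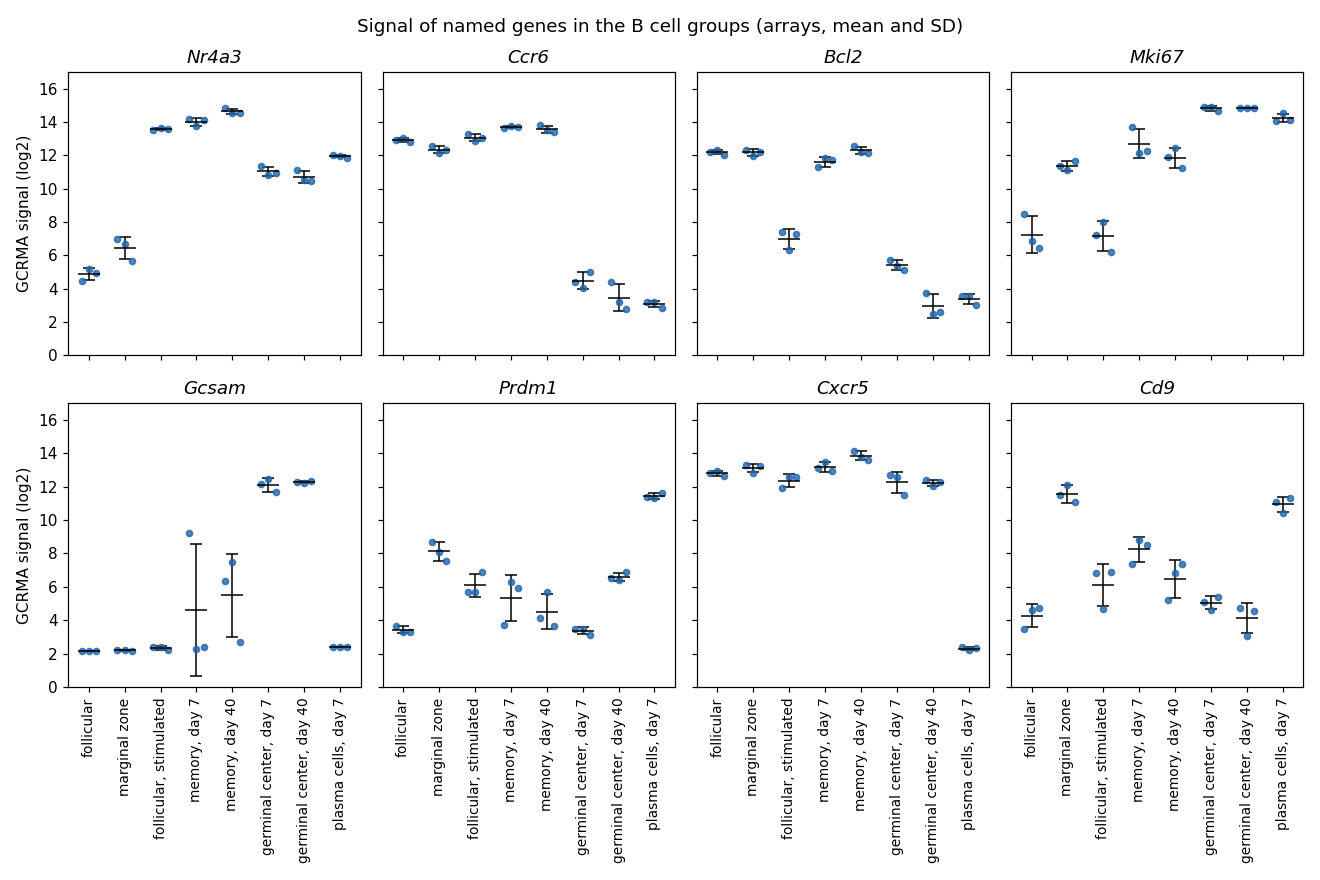
GCRMA signal (log2, y axis) of 8 named genes in the 8 groups (x axis), with points for the 3 arrays of a group and bars for the mean ± SD. Ccr6 stood at 13.69 and 13.56 in memory cells of day 7 and day 40 and at 4.47 and 3.45 in germinal center cells, and Gcsam at 9.21 in replicate 1 of the day 7 memory cells.

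**Figure D2:**
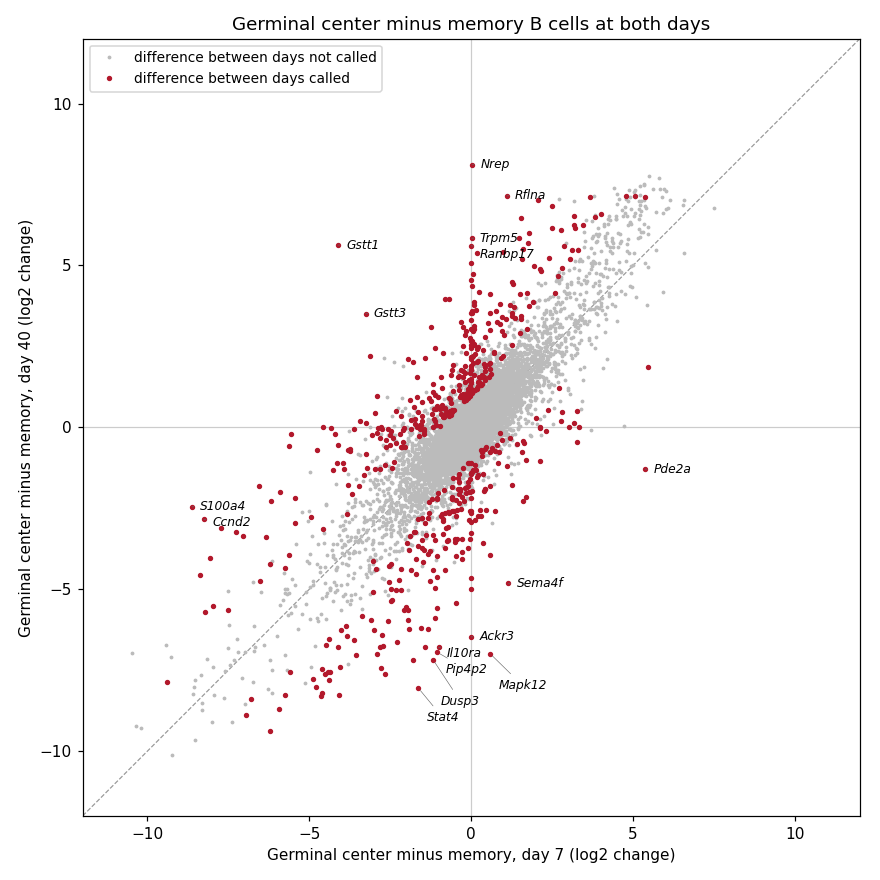
Log2 change between germinal center and memory B cells at day 7 (x axis) and day 40 (y axis) for the 11209 genes tested (points), with the line of equal change dashed. Red points are the 555 genes whose difference was called as changed between the days, and labels name the 8 with the largest rise and the 8 with the largest fall.

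Germinal center cells of day 40 were compared with those of day 7 to ask how the reaction changes with time. Nrep (chromosome 18) rose by 8.26 ± 0.11 (SE), to 10.44 ± 0.06 from 2.18 ± 0.06 (SD, n = 3, adjusted p = 3.77e-20). Fam135a (7.59 ± 0.54), Dmxl2 (7.01 ± 0.34), Osbpl3 (6.50 ± 0.47), Gstt1 (6.09 ± 0.36) and Rflna (6.05 ± 0.37) were higher as well. These had adjusted p values up to 9.71e-09. Stat4 (chromosome 1), a transcription factor of interleukin 12 signalling, fell by 6.89 ± 0.23 (SE), to 3.11 ± 0.61 from 10.00 ± 0.16 (SD, n = 3, adjusted p = 7.48e-14). Uchl1 (-6.75 ± 1.08), Dusp3 (-6.58 ± 0.30), Lgals9 (-6.26 ± 0.36), Il10ra (-5.98 ± 0.32) and Pip4p2 (-5.80 ± 0.25) were lower at day 40. Adjusted p values were at most 2.97e-04. Lgals9 encodes galectin-9 and Il10ra the interleukin 10 receptor. Prdm1 rose by 3.23 ± 0.55, to 6.60 from 3.37, and the changes of Nrep and Uchl1 are lower bounds.

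Of the early activation genes, 4 of 23 rose, 0 fell and 19 were not called (5 and 0 adjusted over the list alone), led by Ier3 (3.68 ± 0.24), Egr2 (1.88 ± 0.44), Egr1 (1.85 ± 0.32) and Nfkb2 (1.37 ± 0.21), the rise of Ier3 being a lower bound. Across the early activation list the median change was 0.75, with an adjusted p = 2.40e-05 (adjusted p = 0.222 with an estimated correlation). The dissociation and heat shock list rose with them: 3 of 20 genes were higher and 0 lower, with a median of 0.485 and an adjusted p = 0.00278 (adjusted p = 0.286 with an estimated correlation). Among migration receptors Itgb7 (-3.30 ± 0.46), Ccr7 (-2.61 ± 0.72), S1pr1 (-2.37 ± 0.57) and S1pr4 (-1.80 ± 0.33) were lower: 0 of 17 rose, 6 fell and 11 were not called (0 and 6 adjusted over the list alone), and 2 fell with the array that had the fewest values at the floor left out of each group. The migration receptor list had a median change of -0.11, with an adjusted p = 0.0290 (adjusted p = 0.347 with an estimated correlation). No mitosis gene was called (limma): 0 of 24 rose, 0 fell and 24 were not called (0 and 0 adjusted over the list alone), 0 higher and 0 lower at an unadjusted p under 0.05. Mki67 stood at 14.85 ± 0.02 against 14.80 ± 0.15. Across the mitosis list the median change was 0.33, and the list did not pass its test (adjusted p = 0.457). The germinal center program gave no call either (limma): 0 of 16 rose, 0 fell and 16 were not called (0 and 0 adjusted over the list alone), 1 higher and 0 lower at an unadjusted p under 0.05. Its largest difference was Rgs13 (1.91 ± 0.89, adjusted p = 0.242). Of 11209 genes tested, 401 were higher and 264 were lower at day 40, and with only these groups in the fit the lower count was 157.

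Plasma cells of day 7 were compared with memory B cells of the same day to describe the antibody-secreting state. Cd28 (chromosome 1), a costimulatory receptor first known from T cells, rose to 13.21 ± 0.36 from 2.21 ± 0.07 (SD, n = 3, adjusted p = 1.98e-22). Bhlha15, the secretory cell regulator Mist1, rose by 10.45 ± 0.12, and Prg2 (9.99 ± 0.39), Selenom (9.77 ± 0.11), Pgam2 (9.70 ± 0.09) and Thbd (9.51 ± 0.46) rose as well. None had an adjusted p above 2.40e-12. The plasma cell regulators Prdm1 (6.13 ± 0.55) and Xbp1 (4.23 ± 0.20) were higher, and so was the sort marker Sdc1 (6.23 ± 0.64), at 14.85 ± 0.06 against 8.62 ± 0.11. Cxcr5 (chromosome 9), the follicle homing receptor, fell by 10.89 ± 0.26 (SE), to 2.30 ± 0.10 from 13.19 ± 0.28 (SD, n = 3, adjusted p = 3.38e-17). Parm1 (-10.72 ± 0.16), Srpk3 (-10.68 ± 0.36), Ccr6 (-10.63 ± 0.29), Tlr1 (-10.58 ± 0.13) and Cd22 (-10.49 ± 0.17) were lower too. The highest adjusted p was 1.00e-14. Because a group lay at background, the changes of Cd28, Selenom, Pgam2 and Cxcr5 are lower bounds.

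Secretory genes rose together: in the plasma cell program, 17 of 18 rose, 0 fell and 1 was not called (17 and 0 adjusted over the list alone), and in the secretory pathway and unfolded protein response, 24 of 27 rose, 0 fell and 3 were not called (24 and 0 adjusted over the list alone). The plasma cell program list had a median change of 3.35, with an adjusted p = 7.58e-11 (adjusted p = 0.0156 with an estimated correlation). For the secretory pathway list the median change was 1.96, with an adjusted p = 5.59e-13 (adjusted p = 0.0130 with an estimated correlation). Examples were Creb3l2 (8.13 ± 0.52), Epcam (7.45 ± 0.43) and Tnfrsf17 (7.24 ± 0.18) and, for the endoplasmic reticulum, Sec24d (8.11 ± 0.43), Sdf2l1 (5.47 ± 0.62) and Creld2 (4.47 ± 0.18). B cell identity genes fell: 0 of 19 rose, 16 fell and 3 were not called (0 and 16 adjusted over the list alone), with Fcer2a (-9.62 ± 0.19) and Cd72 (-9.55 ± 0.18) beside Cxcr5 and Cd22, and the falls of Fcer2a and Cxcr5 are lower bounds. For the B cell identity list the median change was -4.51, with an adjusted p = 4.03e-11 (adjusted p = 0.00176 with an estimated correlation). Antigen presentation by MHC class II fell with them, Cd86 (-9.95 ± 0.28), H2-Oa (-7.67 ± 0.31) and Cd40 (-4.69 ± 0.14) in front: 0 of 13 rose, 11 fell and 2 were not called (0 and 11 adjusted over the list alone). For the class II list the median change was -1.92, with an adjusted p = 1.45e-07 (adjusted p = 0.0402 with an estimated correlation). Mitosis genes were higher than in memory cells: 19 of 24 rose, 0 fell and 5 were not called (19 and 0 adjusted over the list alone), Plk1 (4.21 ± 0.68) and Aurka (4.06 ± 0.72) the most. In the mitosis list the median change was 2.16, with an adjusted p = 0.00106 (adjusted p = 0.665 with an estimated correlation). That count was 23 without memory replicate 1 and 5 with the array that had the fewest values at the floor left out of each group, and for DNA replication, where 12 of 24 rose, it was 17 and 2.

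Of the myeloid markers tested, 6 of 9 rose, 1 fell and 2 were not called (7 and 1 adjusted over the list alone), among them S100a8 (7.36 ± 2.67), Cd14 (6.89 ± 0.60) and Clec7a (6.72 ± 0.41), the rise of Clec7a being a lower bound. The list held 14 markers with a probe set, and the rest were too dim to be tested. A marker could pass that filter through the 3 plasma arrays alone, so these counts overstate how much of the list was raised. For the myeloid marker list the median change was 6.45, and the list did not pass its test (adjusted p = 0.102). T cell markers held 4 higher and 1 lower of 9 tested (12 had a probe set), Cd28 included. NK cell markers held 2 higher and 1 lower of 5 tested (10 had a probe set). For the T cell marker list the median change was 1.07, and the list did not pass its test (adjusted p = 0.140). In all, 2005 genes rose and 2096 fell in plasma cells.

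Plasma cells were also compared with germinal center B cells of day 7, the other antigen-driven population of that day. Oosp1 (chromosome 19) rose by 11.32 ± 0.70 (SE), to 13.57 ± 0.23 from 2.25 ± 0.18 (SD, n = 3, adjusted p = 9.22e-11). Cd28 (11.06 ± 0.12), Bhlha15 (10.65 ± 0.12), Fkbp11 (10.43 ± 0.26), Ccnd2 (10.34 ± 0.31) and Creb3l2 (10.22 ± 0.52) rose as well. These had adjusted p values up to 5.58e-12, and Prdm1 rose by 8.08 ± 0.55. Srpk3 (chromosome X) fell by 10.48 ± 0.36 (SE), to 2.66 ± 0.13 from 13.14 ± 0.31 (SD, n = 3, adjusted p = 1.41e-14). Rassf6 (-10.39 ± 0.64), Cxcr5 (-9.97 ± 0.26), Cd22 (-9.97 ± 0.17), Emid1 (-9.81 ± 0.18) and Gcsam (-9.71 ± 1.28) fell too. Adjusted p values were at most 2.87e-06, and Bcl6 fell by 5.22 ± 0.18. A group at background makes the changes of Oosp1, Cd28, Bhlha15, Cxcr5, Emid1 and Gcsam lower bounds.

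In the plasma cell program, 17 of 18 rose, 0 fell and 1 was not called (17 and 0 adjusted over the list alone), and among secretory genes, 23 of 27 rose, 0 fell and 4 were not called (23 and 0 adjusted over the list alone), Pdia4 (9.64 ± 1.03), Sec24d (8.92 ± 0.43) and Edem2 (5.55 ± 0.42) the largest. For the plasma cell program list the median change was 2.85, with an adjusted p = 8.49e-12 (adjusted p = 0.0130 with an estimated correlation). Across the secretory pathway list the median change was 1.72, with an adjusted p = 9.06e-13 (adjusted p = 0.0130 with an estimated correlation). The germinal center program was lower: 0 of 16 rose, 13 fell and 3 were not called (1 and 14 adjusted over the list alone), with Cd86 (-9.08 ± 0.28), Rgs13 (-8.73 ± 0.89) and Mybl1 (-6.38 ± 1.10) beside Gcsam. For the germinal center program list the median change was -4.44, with an adjusted p = 2.79e-04 (adjusted p = 0.368 with an estimated correlation). B cell identity genes, Ciita (-9.33 ± 0.20) and Cd72 (-8.85 ± 0.18) among them, fell: 0 of 19 rose, 16 fell and 3 were not called (0 and 16 adjusted over the list alone), and the changes of Ciita and Gcsam are lower bounds. Across the B cell identity list the median change was -4.59, with an adjusted p = 5.10e-11 (adjusted p = 0.00176 with an estimated correlation). For MHC class II presentation, 1 of 13 rose, 9 fell and 3 were not called (1 and 9 adjusted over the list alone). Across the class II list the median change was -1.76, with an adjusted p = 6.60e-05 (adjusted p = 0.117 with an estimated correlation). DNA replication genes such as Pola1 (-3.60 ± 0.88) and Mcm10 (-3.28 ± 0.81) were lower than in germinal center cells: 0 of 24 rose, 15 fell and 9 were not called (0 and 15 adjusted over the list alone). The DNA replication list had a median change of -1.45, with an adjusted p = 0.00292 (adjusted p = 0.671 with an estimated correlation). For mitosis, 0 of 24 rose, 10 fell and 14 were not called (0 and 3 adjusted over the list alone), and 5 fell with the array that had the fewest values at the floor left out of each group. The mitosis list had a median change of -1.38, and the list did not pass its test (adjusted p = 0.0820). Myeloid markers were higher here as well: of the 9 tested among 14 with a probe set, 8 rose, 0 fell and 1 was not called (8 and 0 adjusted over the list alone), Lyz2 (8.40 ± 1.42), S100a8 (7.56 ± 2.67) and C1qb (7.33 ± 1.40) the most. Across the myeloid marker list the median change was 7.02, with an adjusted p = 0.00457 (adjusted p = 0.391 with an estimated correlation). The comparison called 2026 genes that rose and 2251 that fell in plasma cells.

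Among naive cells, marginal zone B cells were compared with follicular B cells. Tsga13 (chromosome 6) rose by 9.80 ± 0.51 (SE), to 12.10 ± 0.15 from 2.30 ± 0.14 (SD, n = 3, adjusted p = 4.87e-11). The atypical chemokine receptors Ackr2 (9.45 ± 0.27) and Ackr3 (9.39 ± 0.50) rose too, with Tbc1d9 (8.91 ± 0.38), Nebl (8.53 ± 0.20) and Ffar2 (8.35 ± 0.58), a receptor for short-chain fatty acids, and adjusted p values reached 3.17e-09 at most. Pde2a (chromosome 7), a cyclic nucleotide phosphodiesterase, fell by 7.39 ± 0.44 (SE), to 3.60 ± 0.33 from 10.99 ± 0.11 (SD, n = 3, adjusted p = 2.88e-10). Crip3 (-7.30 ± 0.30), Dusp4 (-7.05 ± 0.19), Car2 (-6.62 ± 0.93), Sdc1 (-6.53 ± 0.64) and Lef1 (-6.50 ± 0.81) were lower as well. None had an adjusted p above 2.90e-05. The sort markers moved with the gates, Fcer2a (CD23) to 8.67 ± 0.29 from 12.97 ± 0.10 and Cr2 (CD21) to 14.22 ± 0.13 from 13.10 ± 0.10. Lower bounds apply to Tsga13, Ackr3 and Car2, each with a group at background.

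Marginal zone markers rose: 9 of 12 rose, 0 fell and 3 were not called (10 and 0 adjusted over the list alone), Myof (7.46 ± 0.26), Cd9 (7.28 ± 0.64), Asb2 (6.61 ± 0.24) and S1pr3 (5.90 ± 0.31) the most, the rise of Asb2 being a lower bound. Across the marginal zone marker list the median change was 3.07, with an adjusted p = 1.08e-11 (adjusted p = 0.0156 with an estimated correlation). Mitosis genes were higher in marginal zone cells: 15 of 24 rose, 0 fell and 9 were not called (16 and 0 adjusted over the list alone), with Nusap1 (5.87 ± 0.62), Ube2c (5.67 ± 0.45) and Prc1 (5.01 ± 0.57). For the mitosis list the median change was 3.57, with an adjusted p = 9.55e-12 (adjusted p = 0.282 with an estimated correlation). Of the quiescence genes, 0 of 20 rose, 5 fell and 15 were not called (0 and 5 adjusted over the list alone), Klf2 (-3.83 ± 0.57), Cdkn2d (-3.16 ± 0.26) and Tsc22d3 (-2.93 ± 0.55) among those that fell. In the quiescence list the median change was -0.55, with an adjusted p = 6.05e-05 (adjusted p = 0.0629 with an estimated correlation). The toll-like receptor pathway had Tlr3 (4.27 ± 0.55), Ly96 (3.23 ± 0.30) and Tlr7 (2.01 ± 0.33) higher: 3 of 14 rose, 0 fell and 11 were not called (3 and 0 adjusted over the list alone). For the toll-like receptor list the median change was 0.62, with an adjusted p = 0.00128 (adjusted p = 0.266 with an estimated correlation). For interferon-stimulated genes, 7 of 17 rose, 0 fell and 10 were not called (7 and 0 adjusted over the list alone), led by Oas2 (3.61 ± 0.43) and Rsad2 (2.82 ± 0.48), and 4 rose with the array that had the fewest values at the floor left out of each group. In the interferon list the median change was 0.57, with an adjusted p = 0.0139 (adjusted p = 0.514 with an estimated correlation). Prdm1 rose by 4.69 ± 0.55 while Bach2 (-2.88 ± 0.36) and Bcl6 (-1.96 ± 0.18) fell. Of 11209 genes tested, 808 rose and 429 fell in marginal zone cells.

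Follicular B cells stimulated for 6 h were compared with unstimulated ones, to describe the first hours of activation. The labels name no group cultured without the antibodies, so effects of culture and of stimulation cannot be told apart. Tent5c (chromosome 3), a poly(A) polymerase, rose by 9.56 ± 0.22 (SE), to 11.88 ± 0.31 from 2.32 ± 0.13 (SD, n = 3, adjusted p = 1.58e-16). The chemokines Ccl4 (9.29 ± 0.89) and Ccl3 (9.25 ± 1.53) rose too, as did Gng4 (9.23 ± 0.15), Il2ra (8.79 ± 0.13), Nr4a3 (8.71 ± 0.26) and Rgs1 (8.69 ± 0.36). The highest adjusted p was 4.09e-05. Il2ra encodes the interleukin 2 receptor alpha chain. Pld4 (chromosome 12) fell by 10.38 ± 0.15 (SE), to 2.74 ± 0.05 from 13.12 ± 0.08 (SD, n = 3, adjusted p = 7.08e-20). Itgb7 (-10.00 ± 0.46), Gimap7 (-9.63 ± 0.38), Acp5 (-9.60 ± 0.23), Slc14a1 (-9.09 ± 0.38) and Ifi213 (-9.09 ± 0.28) fell as well. These had adjusted p values up to 1.94e-12. The transcription factor Myc rose by 3.58 ± 0.63, and the rises of Ccl4, Ccl3, Gng4 and Il2ra are lower bounds because unstimulated cells lay at background.

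Ribosome biogenesis genes and MYC targets rose together: 19 of 22 rose, 0 fell and 3 were not called (19 and 0 adjusted over the list alone), Polr1b (3.79 ± 0.42), Nop16 (3.52 ± 0.28), Rrp9 (3.40 ± 0.29) and Srm (3.34 ± 0.21) the most. For the ribosome biogenesis list the median change was 1.73, with an adjusted p = 9.55e-12 (adjusted p = 0.0519 with an estimated correlation). For early activation genes, 10 of 23 rose, 1 fell and 12 were not called (10 and 1 adjusted over the list alone), and the gene that fell was Fos (-6.70 ± 0.43). In the early activation list the median change was 0.76, with an adjusted p = 9.91e-04 (adjusted p = 0.333 with an estimated correlation). Interferon-stimulated genes fell: 0 of 17 rose, 15 fell and 2 were not called (0 and 15 adjusted over the list alone), Xaf1 (-7.28 ± 0.28), Ifit3 (-7.26 ± 0.48) and Usp18 (-7.13 ± 0.62) in front, with the falls of Ifit3 and Usp18 lower bounds. The interferon list had a median change of -3.94, with an adjusted p = 9.22e-07 (adjusted p = 0.209 with an estimated correlation). Quiescence genes such as Cdkn2d (-7.52 ± 0.26), Klf2 (-5.41 ± 0.57) and Tsc22d3 (-4.77 ± 0.55) fell: 1 of 20 rose, 14 fell and 5 were not called (1 and 14 adjusted over the list alone), and another probe set of Tsc22d3 pointed the other way. The quiescence list had a median change of -2.04, with an adjusted p = 3.58e-04 (adjusted p = 0.0906 with an estimated correlation). B cell identity genes were lower too: 0 of 19 rose, 12 fell and 7 were not called (0 and 12 adjusted over the list alone), with Cd22 (-3.56 ± 0.17), Pax5 (-3.40 ± 0.50) and Fcer2a (-3.01 ± 0.19). In the B cell identity list the median change was -1.13, with an adjusted p = 9.83e-06 (adjusted p = 0.0189 with an estimated correlation). In the toll-like receptor pathway, 0 of 14 rose, 9 fell and 5 were not called (0 and 9 adjusted over the list alone), and Tlr3 (-5.41 ± 0.55) and Tlr4 (-4.99 ± 0.80) fell most. Across the toll-like receptor list the median change was -1.50, with an adjusted p = 0.00214 (adjusted p = 0.281 with an estimated correlation). For mitosis genes after 6 h, 2 of 24 rose, 3 fell and 19 were not called (0 and 2 adjusted over the list alone), and 0 rose with the array that had the fewest values at the floor left out of each group. Across the mitosis list the median change was -0.21, and the list did not pass its test (adjusted p = 0.922). In all, 1891 genes were higher and 2514 lower in the stimulated cells, where culture may contribute. Stimulated arrays had fewer probe sets at the floor than unstimulated ones (38.3% ± 1.82 against 41.9% ± 2.20, SD, n = 3 per group) and a higher signal of the B1 repeat probe set (14.11 ± 0.38 against 13.39 ± 0.33, log2), each with an exact two-sided permutation p = 0.2, where 3 arrays against 3 cannot go below 0.1.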

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

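Tests of the myeloid lists, of handling and of cell division were chosen after the result was seen, as was a wider bound in the test for admixed germinal center cells, while the splits of arrays and the other tests were chosen before the data were examined.

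The difference between germinal center and memory B cells itself changed between day 7 and day 40: by the interaction test (limma), it was higher at day 40 for 327 genes and lower for 228. The largest increases were those of Gstt1 (9.74 ± 0.51), Nrep (8.08 ± 0.16), Gstt3 (6.77 ± 0.77), S100a4 (6.17 ± 0.71), Rflna (6.05 ± 0.52), Trpm5 (5.82 ± 0.11), Ranbp17 (5.61 ± 0.20) and Ccnd2 (5.41 ± 0.44), as log2 change ± SE. The SE rests on variance pooled over all groups of 3 arrays. The largest decreases were those of Mapk12 (-7.58 ± 0.37), Pde2a (-6.66 ± 0.62), Ackr3 (-6.47 ± 0.71), Stat4 (-6.43 ± 0.32), Dusp3 (-6.00 ± 0.43), Sema4f (-5.97 ± 0.69), Pip4p2 (-5.91 ± 0.35) and Il10ra (-5.78 ± 0.45). Gstt1, a glutathione transferase, stood at 3.97 ± 0.43 in germinal center and 8.09 ± 0.87 in memory cells at day 7, and at 10.07 ± 0.07 and 4.44 ± 0.82 at day 40 (SD). Nrep, Rflna, Trpm5 and Ranbp17 were high in germinal center cells of day 40 alone among these 4 groups, at 10.44, 9.30, 7.99 and 7.76. Signal over background limits the values of Nrep, Rflna, Trpm5, Ranbp17 and Ackr3, for which at least 2 of the 4 groups lay at background, so their ranks are uncertain. Each had an SD of 0 in at least 1 group at the floor, which lowers its SE and p. Dusp3 had another probe set that pointed the other way, and its call ended with the mean of the probe sets. Of the plasma cell list, 5 of 18 rose, 0 fell and 13 were not called (5 and 0 adjusted over the list alone). Across the plasma cell program list the median change was 0.60, with an adjusted p = 1.29e-05 (adjusted p = 0.0937 with an estimated correlation). Of the mitosis list, 2 of 24 rose, 0 fell and 22 were not called (7 and 0 adjusted over the list alone), and 1 rose without memory day 7 replicate 1. With days shuffled within each cell type, 1 of 100 splits of the arrays, the real split, gave as many as 555 genes, and the highest of the others gave 552, with the germinal center days kept and 2 memory arrays of each day exchanged, while splits that exchanged 1 or 2 arrays of each day in both cell types gave at most 7. That share lay under 0.05, but it cannot exclude chance for the interaction by itself, since splits that keep the days of a single cell type keep its day difference. Nor can it exclude a batch tied to the day, or chance if the 3 arrays of a group are technical, which the labels leave open. No biological explanation was tested.

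Replicate 1 of the day 7 memory cells lay toward germinal center B cells, and the values argue against a wrong label. Genes high in the other memory replicates and near background in germinal center cells stood 7.47 above the germinal center level in it. As a test of cell division alone, 77.3% of 97 genes higher in germinal center cells and not raised in plasma cells were raised by 1 or more, where the 97 replaced a set that held too few genes. That test cannot decide, since plasma cells had 15 of 24 DNA replication genes and 10 of 24 mitosis genes lower than germinal center cells. Division genes can therefore remain among the 97. Germinal center B cells mixed into the sample stay open as a source too: their share, estimated from 11 genes near background in the other replicates, would be 20.2% (quartiles 11.6% to 35.5%), and the rise of those 11 genes cannot test it, since the share was computed from it. Against it, memory genes changed by a median of -0.93 where that share predicts -0.32, which missed the bound of 0.5 written beforehand; the bound was widened after this value was seen because the upper quartile of the share predicts -0.63, so the explanation stays undecided. Replicate 1 also had the lowest 3' minus 5' differences of its group, at 0.47 for Actb (0.86 and 1.02 in the others) and 0.59 for Gapdh (1.25 and 1.41). Whether this bears on the pattern was not tested. The sort gate on CD38 and PNA was meant to remove germinal center cells, but its purity was not measured here, and no biological explanation was tested.

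Myeloid genes were high in plasma cells. Of the eosinophil list 42.9% was higher than in germinal center cells, with Prg2 at 12.35 but Siglecf at 2.37 and Ccr3 at 2.15. The list met a bound against eosinophils, but that bound was added after these values were seen and rests on genes near the floor. Eosinophils therefore stay undecided. Neutrophils may be a source, with 70% of the list higher (S100a9 14.20, S100a8 13.29, Camp 11.14) but Cxcr2 at 2.15 and Csf3r at 2.96. Macrophages may be another, with 50% higher (Lyz2 13.16, Mrc1 10.91, C1qb 10.48) but C1qa at 2.42 and Cd163 at 2.15. Apoe of that list was lower, at 6.45 against 10.4 in germinal center cells. Neutrophils and macrophages stay open because part of each list was raised and part was not. The gate on CD138 and the lambda chain was meant to remove such cells, but its purity was not measured here. The monocyte and dendritic cell list had 36.4% higher and was not weighed as a source. No biological explanation was tested.

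Early activation genes were higher in memory than in follicular B cells at both days, beside genes known to respond to tissue dissociation and heat shock. Handling of immunized spleens may have raised them, but acting alike on memory and germinal center cells it would leave no difference between these: the list mean of 20 genes was higher in memory cells by 1.01 at day 7 and 1.16 at day 40. The lowest memory array exceeded the highest germinal center array by 0.41 and 0.83, and the bound of 0.5 was not met at day 7, so this stays undecided. List means were 9.59 in follicular, 11.50 in day 7 memory, 12.43 in day 40 memory, 10.50 in day 7 germinal center, 11.27 in day 40 germinal center and 12.05 in plasma cells, against 9.21 in marginal zone cells. Immunization, which the follicular cells lack, stays an open biological explanation and was not tested. Memory cells were also sorted by binding the hapten while follicular cells were not, so an effect of that step cannot be told apart from immunization.

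Probe sets without 1 gene symbol, which no comparison above uses, also differed between day 40 memory and follicular B cells: of 5052 tested, 296 were higher and 485 lower.

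For the 10 comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes. Genes called higher and lower in the real split, and the most called in another, were day 7 memory against follicular cells (1029 and 1031, highest other 10), day 40 memory against follicular cells (810 and 733, highest other 3), day 40 against day 7 memory cells (306 and 256, highest other 43), germinal center against memory cells at day 7 (1299 and 1356, highest other 22) and germinal center against memory cells at day 40 (1713 and 1415, highest other 7). For the later comparisons they were germinal center cells of day 40 against day 7 (401 and 264, highest other 14), plasma against memory cells (2005 and 2096, highest other 21), plasma against germinal center cells (2026 and 2251, highest other 10), marginal zone against follicular cells (808 and 429, highest other 9) and stimulated against unstimulated cells (1891 and 2514, highest other 718).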

How the results depend on the processing

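The low-floor alternative, with the array that had the fewest values at the floor left out of each group, and the share at the floor as a covariate were chosen after the data were examined, and the other alternatives before. No called gene among the largest changes and the index genes changed sign, nor did a list test past its threshold, in the alternatives run for each, and leaving out each array in turn moved no total count by more than 1.5 times. The direction of 3 list counts did turn: DNA replication genes in day 7 memory against follicular cells went from 4 higher and 0 lower (median 0.40) to 2 higher and 4 lower (median -0.10) without memory day 7 replicate 1, the same list in the interaction from 0 higher and 1 lower (median 0.03) to 1 higher and 0 lower (median 0.62) with the low-floor arrays left out (median -0.55 without replicate 1), and mutation and repair genes in plasma against memory cells from 5 higher and 2 lower (median 0.42) to 2 higher and 3 lower (median 0.07) with the low-floor arrays left out. Correlation across genes between the days ranged from 0.841 to 0.872. A block for the replicate number gave 1036 higher and 1037 lower genes for day 7 memory against follicular cells. The labels do not say whether these numbers pair the samples, and in no comparison did every same-numbered pair correlate over 0.1. The array with the fewest values at the floor was replicate 2 in each group but the follicular one. A batch shared by number thus stays possible, and the low-floor alternative mostly leaves out replicate 2. Estimated instead of preset correlation ended 90 list calls. The mean of a gene's probe sets, dim ones included, ended the calls of 9 of 285 named results and lowered others by more than 1.5 times, among them Nr4a3 in day 40 memory cells (3.87 against 9.77) and Bhlha15 in plasma against memory cells (5.23 against 10.45), each still called.

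With the stricter filter, which tests fewer genes, 617 genes were lower in day 7 memory and 428 in day 40 memory than in follicular cells, 187 were higher in day 40 than in day 7 memory cells, 219 in germinal center cells of day 40 than of day 7, 491 in marginal zone cells, 1206 with stimulation, and 187 in the interaction. With no minimum change, which admits smaller changes, the counts higher and lower were 1763 and 1924 for day 7 memory against follicular cells, 1231 and 1387 for day 40 memory, 539 and 601 between the memory days, 2453 and 2222 for germinal center against memory cells at day 7, and 2951 and 2348 at day 40. Under the same setting 424 genes were lower in germinal center cells of day 40 than of day 7, 3186 and 3500 lower in plasma cells than in memory and germinal center cells, 763 lower in marginal zone cells, and 2924 higher with stimulation. Array weights gave 505 higher and 403 lower between the memory days and 597 and 378 in the interaction. Only the compared groups in the fit gave 105 and 94 between the memory days and 157 lower between the germinal center days. With the low-floor arrays left out, 150 and 140 were called between the memory days and 185 higher in the interaction, with fewer arrays in the fit. For array weights and the groups in the fit, the cause was not tested.

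Signal over background limits the largest changes, since a gene at the floor of 2.15 gives only a lower bound.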

Other observations

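List values not described above were computed for every comparison with the tests planned before the data were examined. For oxidative phosphorylation genes in germinal center against memory cells, at day 7, 1 of 25 rose, 0 fell and 24 were not called (1 and 0 adjusted over the list alone), with 3 higher without memory replicate 1, and at day 40, 3 of 25 rose, 0 fell and 22 were not called (3 and 0 adjusted over the list alone). For the oxidative phosphorylation list the median change was 0.48, with an adjusted p = 9.45e-05 (adjusted p = 0.291 with an estimated correlation). Across the oxidative phosphorylation list the median change was 0.63, with an adjusted p = 3.16e-05 (adjusted p = 0.281 with an estimated correlation). In stimulated cells, for glycolysis, 6 of 15 rose, 1 fell and 8 were not called (6 and 1 adjusted over the list alone). For the glycolysis list the median change was 0.75, with an adjusted p = 0.00181 (adjusted p = 0.209 with an estimated correlation). In the BCL2 family, Bcl2 fell by 5.21 ± 0.31 and Bcl2l1 rose by 3.46 in stimulated cells, where 5 of 11 rose, 4 fell and 2 were not called (5 and 4 adjusted over the list alone). For the BCL2 family list the median change was 0.15, and the list did not pass its test (adjusted p = 0.870). Its mean had the other sign (-0.21).

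Of the NK cell list in plasma against memory cells, 2 of 5 tested rose, 1 fell and 2 were not called (2 and 1 adjusted over the list alone), where 10 had a probe set. For the NK cell marker list the median change was 0.03, and the list did not pass its test (adjusted p = 0.914). Of the erythroid and platelet list, 1 gene was tested, and it was not called in plasma cells against memory cells (limma). Among the sort markers, 5 of 10 rose, 4 fell and 1 was not called (5 and 4 adjusted over the list alone) in plasma against memory cells.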
